A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

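The series measured where histone H4 carries O-linked N-acetylglucosamine on threonine 71 (H4T71Gc) by chromatin immunoprecipitation and sequencing with the monoclonal antibody 20H3. Per the labels' protocols, chromatin was cut enzymatically, and the mouse cells were J1 embryonic stem cells (mESC) kept for 96 h in medium with 25 mM glucose, the usual condition, or with 1 mM glucose. The human cells were the embryonic stem cell line H9 (hESC) and the induced pluripotent stem cell line 201B7 (hiPSC), the latter grown on a mouse feeder layer per the labels' protocols. Of the 8 samples, 4 are immunoprecipitated libraries with a deposited peak list and 4 are inputs. The input libraries were used only by the authors, as the control for peak calling, and were not analysed here.

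Reads were aligned with Bowtie2 2.3.4.2 and peaks were called with MACS 1.0.1, per the submitters' processing notes, on the mouse build mm10 and the human build hg38. Per the labels' protocols, peaks were called with input reads as the control, with a tag size of 25 bp, a bandwidth of 300 bp and p cutoffs written as 10e-03 for mouse and 10e-05 for human. The title and treatment of the 1 mM input name 1 mM glucose while its source name gives the 25 mM condition, so which input was the control of the 1 mM list is uncertain, and every 1 mM count rests on that list. The deposited files hold a position and a score for each peak, and the score is taken as -10 times the base 10 logarithm of the peak's p, as this caller writes it. The lowest scores were 30 in both mouse lists and 50 in both human lists, which stand for p of 1e-03 and 1e-05. The mouse lists therefore reach down to weaker peaks than the human lists, and scores were used only to rank or filter peaks within a list. Read depth is not given in the sources used here, so the lists carry no depth per library, and the number of peaks in a list moves with a depth that is unknown.

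Peaks on sequences outside the assembled chromosomes were counted and otherwise left out. No peak ran past the end of its chromosome in the reference sequences of the same builds. Genes came from GENCODE annotations of the same builds, with 21938 protein-coding genes in mouse and 20033 in human. A peak was placed by its midpoint, in this order: promoter (within 1000 bp of a protein-coding transcription start site, TSS), 5' untranslated region (UTR), coding exon, 3' UTR, other exon, intron, up to 5000 bp beyond the gene end, and intergenic. The share within genes counts midpoints from TSS to gene end. Shares carry exact Clopper-Pearson intervals at 95%. The background was 1000 random placements of the same peaks, each kept on its chromosome and outside assembly gaps. In a second background the placements were also matched on GC content, in bins of 2% over 1000 bp windows.

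Peaks of a pair of lists were called shared when they overlapped by at least 1 bp. A gene had a peak when a peak touched it anywhere from 1000 bp upstream of its start to its end. Counts of genes with a peak in both lists were set against 10000 draws of genes matched on length in 20 bins, since long genes are hit more often. For mouse against human, symbols were matched after upper-casing where each occurred once in both annotations. The 20 fixed gene lists were cytosolic ribosomal proteins, proteasome subunits, oxidative phosphorylation, glycolysis and lactate export, hexosamine pathway and O-GlcNAc cycling, glucose-responsive and integrated stress response genes, pluripotency, chromatin and transcription regulators, cell cycle and replication, replication-dependent histones, HOX clusters, early lineage regulators, neuronal function, effectors of liver, muscle and blood, fibroblast and feeder genes, olfactory receptors, vomeronasal and taste receptors, keratin-associated proteins, zinc finger genes named ZNF or Zfp, and clustered protocadherins. Each list's number of members with a peak was set against 10000 random lists of the same size matched on gene length. A list was called above or below when its count lay outside the central 95% of the random lists.

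The gene lists, the comparisons, the rule for named genes and the alternatives, apart from those given below as added, were fixed before the data were examined. Tests of explanations were written after the peak lists had been seen, and those of GC content after the result they measure. The rule names, for each library, the 10 protein-coding genes with the highest-scoring peaks. For each pair of lists it names the 10 genes with the highest-scoring peak that has no peak of the other list within 1000 bp, in each direction, and the 10 genes whose shared peak has the highest smaller score. It also names up to 3 members with the highest-scoring peak from each list, the first 2 members without a peak in alphabetical order where most members have none, and OGT, OGA, POU5F1, NANOG, SOX2 and TXNIP in every library. The text names from the top of each group, leaving out gene models without a usable symbol.

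Each group is 1 library, so nothing was tested between conditions or cell types. The alternatives were score cutoffs of 50 and 100, a promoter of 2500 bp on each side, any overlap in place of the midpoint, all annotated genes, autosomes only, merging of peaks within 1000 bp, reciprocal overlap of 50%, a distance of 1000 bp for sharing, equal numbers of top peaks, the upper part of a list by score, peaks near the TSS only, and backgrounds matched on GC content. Leaving out chromosomes 8 and 11 in mouse or chromosome 1 in human, and GC-matched placements for the sharing of peaks, were added after seeing the data. Lists near the TSS were also compared with random lists matched on promoter GC content, a combination that was not among the alternatives fixed beforehand. Ratios for chromosome regions carry intervals from 10000 bootstrap draws of 10 Mb bins. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

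The procedures were tested on simulated data. Peak lists of the real sizes, made with promoter shares of 21.8%, 21.8%, 21.9% and 21.9% (25 mM mESC, 1 mM mESC, hESC, hiPSC), gave back 21.4%, 21.3%, 21.7% and 21.6%. Simulated sharing of 10.6%, 10.6%, 13.3% and 13.1% came back as 10.4%, 10.8%, 13.3% and 13.0%. Of 200 peak lists per library placed at random, 5, 13, 12 and 8 fell outside the random range. Of 200 random gene lists per library, 12, 8, 8 and 8 were called. Of 50 lists of 40 genes per library drawn so that genes with a peak were 3 times as likely, 36, 31, 40 and 44 were called above. Counting each simulated peak on a chromosome arm 2 times gave a ratio of 2.01 on average over 20 simulations (range 1.92 to 2.11). That ratio was fixed near 2 by the doubling, so it checks the counting only. It does not show how extra DNA copies change the number of called peaks, and the bootstrap was not part of it.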

Results

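H4T71Gc, O-linked N-acetylglucosamine on threonine 71 of histone H4, was mapped in 4 pluripotent cell libraries. A pair of libraries came from mouse J1 embryonic stem cells (mESC) grown for 96 h in 25 mM or 1 mM glucose. The other libraries came from the human embryonic stem cell line H9 (hESC) and the human induced pluripotent stem cell line 201B7 (hiPSC), which was made from fibroblasts with retroviral vectors carrying POU5F1, SOX2, KLF4 and MYC. The deposited lists held 7503 peaks in 25 mM mESC, 6581 in 1 mM mESC, 32281 in hESC and 34070 in hiPSC. They covered 7.004, 5.99, 33.7 and 33.5 Mb, with median peak widths of 808, 809, 885 and 838 bp. Median scores were 35.3 in 25 mM and 34.6 in 1 mM mESC, near the lowest score of 30 in these lists, and 4 and 3 peaks reached a score of 100. In hESC and hiPSC, where the lowest score is 50, the medians were 60.6 and 59.5, and 2526 and 2621 peaks reached 100.

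Every group was a single library, so no comparison has a replicate check. Intervals are exact Clopper-Pearson 95% intervals over peaks and cover counting error only, read depth is unknown, and no p is given across genes. Positions among random placements or random gene lists describe these libraries only. Random lists draw genes singly. Where list members lie side by side in the genome, neighbours can share a peak or its absence, and the random range may be too narrow. Scores are the authors' own and are compared within a list. The mouse and human lists were called at different cutoffs, so their sizes are not comparable.

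The series title names active gene regions, and the first question was where peaks lie relative to genes. Peaks were concentrated just downstream of gene starts: in the first 500 bp after a TSS they were 5.27 times as frequent as random placement in 25 mM mESC, 4.06 times in 1 mM mESC, 3.38 times in hESC and 5.31 times in hiPSC. Examples at promoters were Txnip, which encodes the glucose-induced thioredoxin-interacting protein, in 25 mM mESC (score 64.2, mm10 chromosome 3, 96557511 to 96558688), and Pgk1, which encodes a glycolytic kinase, in 1 mM mESC (83.2, chromosome X, 106186563 to 106187510). In hESC and hiPSC, the promoter of PKM, the pyruvate kinase gene, held peaks with scores of 103 and 120 (hg38 chromosome 15, 72230451 to 72231707 and 72230620 to 72231920). Coding exons were hit 2.24, 2.35, 3.43 and 3.68 times as often as by random placement in 25 mM mESC, 1 mM mESC, hESC and hiPSC, and intergenic sequence 0.861, 0.837, 0.705 and 0.532 times. Against placements also matched on GC content these ratios were 1.05, 1.45, 1.19 and 1.27 for coding exons and 1.07, 0.981, 0.943 and 0.722 for intergenic sequence, so that in 25 mM mESC coding exons lay within the matched range and intergenic sequence above it. The profiles around the TSS and along genes were not set against GC-matched placements.

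Promoters held 5.71% of peaks in 25 mM mESC (427 of 7477, interval 5.20 to 6.26%) and 4.86% in 1 mM mESC (319 of 6561, 4.35 to 5.41%). They held 5.42% in hESC (1737 of 32071, 5.17 to 5.67%) and 8.22% in hiPSC (2790 of 33926, 7.93 to 8.52%). Random placement gave 2.20%, 2.24%, 2.38% and 2.38%, so that the observed shares were 2.59, 2.17, 2.28 and 3.46 times higher. The intervals of the mouse lists overlapped, and those of hESC and hiPSC did not. Peaks within genes made up 48.3%, 49.6%, 59.7% and 67.4%, or 1.16, 1.18, 1.27 and 1.42 times random placement. Most of these lay in introns, which held 38.5%, 40.5%, 45.8% and 50.2% of all peaks, against 36.8%, 37.04%, 41.4% and 41.6% by random placement. Peak sequences had a median GC content of 48.3%, 47.1%, 54.2% and 54.2%, against genome medians of 41.4% in mouse and 39.8% in human. When placements were also matched on GC content, promoter shares were 1.03, 1.18, 0.5999 and 0.921 times the matched mean, and the shares within genes 0.954, 1.02, 1.05 and 1.17 times. Only the promoter share of 1 mM mESC and the shares within genes of hESC and hiPSC stayed above the matched range. The promoter shares of hESC and hiPSC and the share within genes of 25 mM mESC lay below it.

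**Figure D1:**
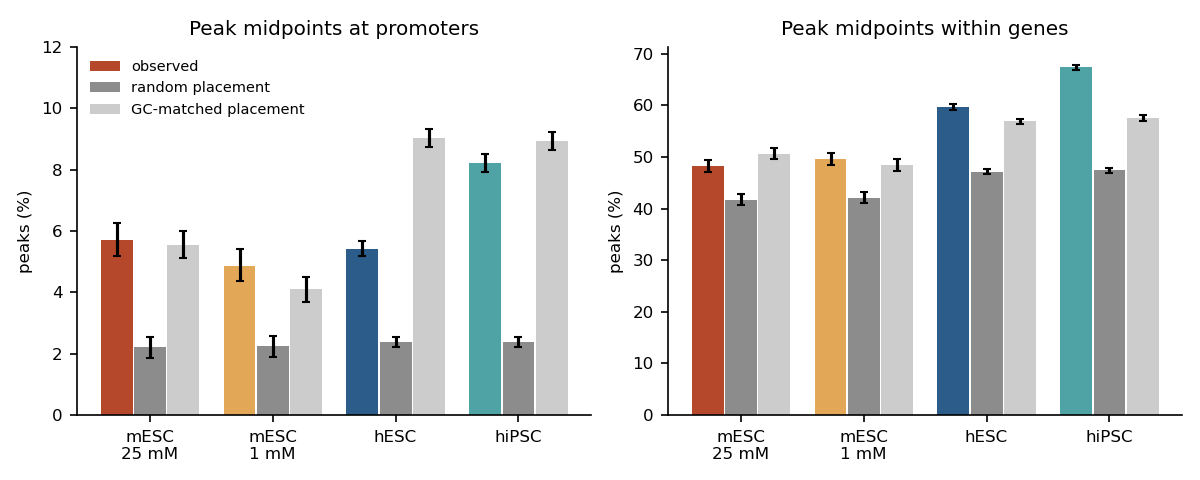
Percent of peak midpoints at promoters (within 1000 bp of a TSS, left) and within protein-coding genes (right) in each library: coloured bars are observed with exact 95% intervals, dark grey bars are the mean of random placements and light grey bars the mean of GC-matched placements, each with its central 95% range. All 4 observed shares exceed random placement in both panels, while at promoters the hESC share of 5.42% lies below its GC-matched mean.

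**Figure D2:**
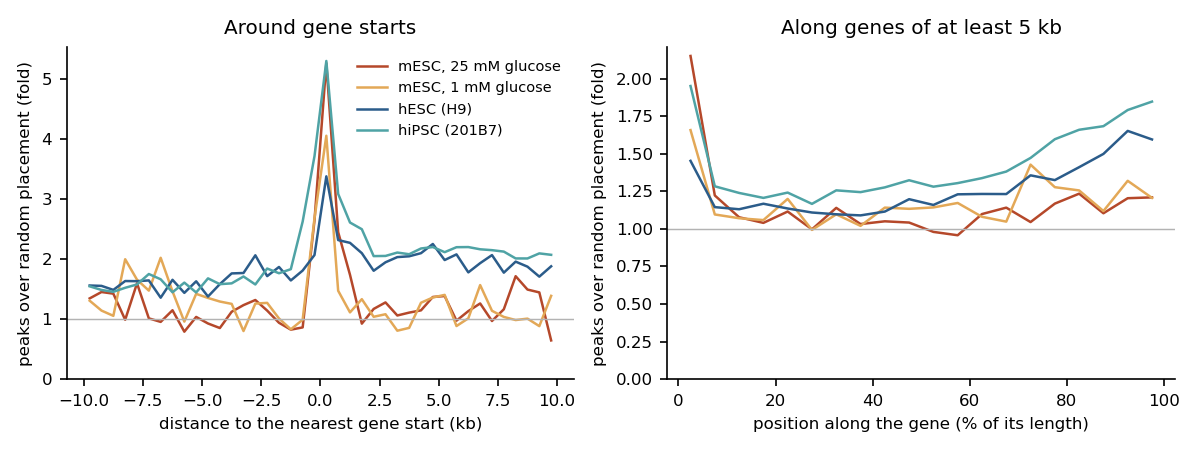
Peaks over random placement (fold) in 500 bp bins around the nearest TSS (left, kb) and in bins of 5% along genes of at least 5000 bp (right, percent of gene length), 1 line per library. All 4 lines are highest in the bin just after the TSS, at 3.38 to 5.31 times random placement.

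Along genes of at least 5000 bp, the first 5% of the gene body was hit 2.15 and 1.66 times as often as by random placement in 25 mM and 1 mM mESC, and the last 5% 1.21 times in both. In hESC the gene end exceeded the gene start (1.60 against 1.45 times), and in hiPSC both ends were raised, 1.95 times at the start and 1.85 times at the end. Scores hardly differed by location. Median scores at promoters, elsewhere in genes and outside genes were 35.6, 35.2 and 35.4 in 25 mM mESC, 35.1, 34.5 and 34.7 in 1 mM mESC, 60.3, 61.0 and 59.9 in hESC, and 60.2, 59.8 and 58.6 in hiPSC.

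The glucose comparison asks whether the mark moves when mESC are held in 1 mM instead of 25 mM glucose. In 25 mM mESC the highest-scoring peaks in protein-coding genes lay in Dnah7b, an axonemal dynein gene (110.0, coding exon, chromosome 1, 46141835 to 46142184), Megf11 (102, intron, chromosome 9, 64510666 to 64512371), and Scap, which encodes the escort protein of the sterol-regulated SREBP transcription factors (89.8, intron, chromosome 9, 110342157 to 110343178). The bone morphogenetic protein receptor gene Acvr1 (85.6), the DNA helicase gene Brip1 (85.5), Vat1l (85.0), the kinase gene Nlk (80.6), the LIM homeobox gene Isl2 (80.0), Tex9 (79.7) and Cmtm8 (79.2) followed. None of these 10 peaks had a 1 mM peak within 1000 bp. Of all 25 mM peaks only 2.15% overlapped a 1 mM peak, so this does not set these 10 apart. The strongest peaks in protein-coding genes of 1 mM mESC without a 25 mM peak nearby lay at the promoter of the uncharacterised gene Gm36079 (98.8), in an intron of Vwa8 (89.4), at the Pgk1 promoter (83.2), in Mmd (81.2), in the 3' UTR of Fbxo28 (78.6), and in an intron of Ogdh, which encodes a subunit of a citric acid cycle enzyme complex (76.9, chromosome 11, 6318136 to 6319729). The stress-induced Sesn1 (76.5), the phosphatase gene Ptprg (75.6), and the shared promoter of Hps5 and Gtf2h1, a subunit gene of transcription factor TFIIH (75.4), came next.

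Few peaks were common to both glucose conditions. Of the 25 mM peaks, 161 (2.15%, interval 1.84 to 2.51%) overlapped a 1 mM peak, and of the 1 mM peaks 160 (2.44%, 2.08 to 2.84%) overlapped a 25 mM peak. Random placement gave 0.575% and 0.651%, and GC-matched placement 1.03% and 1.26%, so the overlap was 3.74 times random and 2.10 and 1.93 times GC-matched placement. Even among the 100 highest-scoring peaks, only 2 of 25 mM and 3 of 1 mM mESC were shared. The strongest shared peaks in protein-coding genes, by the smaller of both scores, lay in the zinc finger gene Zfp985 (60.8), at the promoter of Gm21188 (56.7), in the protein kinase C gene Prkca (45.1), in the kinase gene Mast2 (43.3), in the 3' UTR of the inositol kinase gene Ipmk (40.6), and in introns of Slc10a7 (38.0), the calcium channel gene Itpr2 (37.3) and Snx29 (36.7). Zfp985, Gm21188 and Gm36079 belong to families with close copies in the genome, so reads there can come from more than 1 locus. With 1 list per condition, a peak in only 1 of the lists is a difference between lists and was not shown to be one between glucose levels.

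At the level of genes, 2893 of 21938 protein-coding genes (13.2%) had a peak in 25 mM mESC and 2557 (11.7%) in 1 mM mESC. Both lists hit 911 genes, against 684 (650 to 719) for length-matched draws, while 1982 were hit in 25 mM only and 1646 in 1 mM only. Near the TSS, 559 and 422 genes had a peak and 21 had one in both, against 11.7 (6 to 18) by length-matched draws. Peaks were dense on chromosomes 8 and 11 in both lists: chromosome 8 held 1.61 and 1.80 times, and chromosome 11 held 1.46 and 1.91 times, the number given by its GC content in 25 mM and 1 mM mESC, while chromosome 19 held 0.480 and 0.452 times. Brip1, Nlk, Prkca, Mmd and Ogdh are on chromosome 11 and Vat1l and Slc10a7 on chromosome 8.

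Glucose-responsive and stress response genes were hit within the random range in both mouse lists. The 25 named glucose-responsive and integrated stress response genes matched 26 annotated gene records, because a symbol can occur more than once. Of these records, 3 had a 25 mM peak, against 2.299 (0 to 5) in random lists. The peaks lay at the promoter of Txnip (64.2), at the promoter of the stress transcription factor gene Atf3 (56.5, chromosome 1, 191181862 to 191185302) and in a coding exon of the serine synthesis gene Phgdh (53.2). In 1 mM mESC 1 member had a peak, Atf3, in an intron (31.7), against 1.90 (0 to 5). All 3 of the 25 mM peaks passed a score of 50. At that cutoff random lists held at most 1 such gene in their central 95%, and the observed count was 15.3 times their mean. That cutoff is an alternative setting, the excess rests on 3 peaks, and 5 of 382 alternative gene list values newly left the range. Arrdc4, another glucose-induced gene, and Asns had no 25 mM peak. Glycolysis genes were hit 4 and 3 times among 22 annotated records of 21 named genes. Ldha, Slc2a3 (46.3) and Hk1 (44.8) led in 25 mM, and Pgk1, Ldhb (38.5) and Slc2a3 (30.4) were hit in 1 mM. In the hexosamine pathway, which makes the sugar donor of O-GlcNAc, 1 of 12 genes was hit in each list, Gfpt1 (36.1), the rate-limiting step, in 25 mM and Gnpnat1 (31.97) in 1 mM. Ogt and Oga, the genes of the enzymes that add and remove O-GlcNAc, had no peak in either list.

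Chemoreceptor families were hit less often than length-matched genes in both mouse lists. Many of these genes lie in clusters, which random lists do not copy. Olfactory receptors were hit in 11 of 1135 genes in 25 mM mESC, against 41.9 (31 to 54) in random lists, and in 16 in 1 mM mESC, against 30.9 (21 to 41). With random lists also matched on the GC content of promoters, neither olfactory count lay outside the random range. Vomeronasal and taste receptors were hit in 1 and 4 of 365 genes, against 23.7 (15 to 33) and 20.9 (13 to 30), and with promoter GC content matched against 11.3 (6 to 18) and 14.4 (8 to 22). Near the TSS they were hit in 0 and 1 genes, below length-matched lists (7.42, 3 to 13, and 6.36, 2 to 12) but within the range of lists also matched on promoter GC content (2.33, 0 to 6, and 2.59, 0 to 6). At a score of at least 50, where few peaks are left, neither family lay outside the range in either list. Of 57 clustered protocadherins, adhesion genes of neurons, 24 were hit in 25 mM, against 13.5 (8 to 19), and 0 in 1 mM, against 12.2 (7 to 18). The 24 rest on 2 peaks, of which the stronger lies within the overlapping transcription units of many Pcdhg genes (49.7, coding exon, chromosome 18, 37807924 to 37808899), and no member was hit within 1000 bp of a TSS. Random lists do not copy such clustering.

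The other mouse lists lay within the random range. Pluripotency genes were hit in 6 of 35 in 25 mM mESC, led by introns of Tet1 (39.96), Lin28b (39.6) and Esrrb (34.8), and in 3 in 1 mM mESC, Mycn (38.5), Tfcp2l1 (33.0) and Esrrb (30.2). Pou5f1, Nanog and Sox2, the core pluripotency factors, had no peak in either list. Counts in 25 mM and 1 mM mESC were 3 and 2 of 80 cytosolic ribosomal proteins (Rpl23 at 46.2 and Rpl4 at 43.9 led), 4 and 4 of 32 proteasome subunits, 4 and 7 of 75 oxidative phosphorylation genes (Cox7c at 58.1 in 1 mM), 7 and 9 of 42 chromatin regulators (Polr2a at 42.6 and Chd8 at 42.9 led), and 3 and 3 of 35 cell cycle genes. Replication-dependent histones were hit in 0 and 1 of 67, HOX genes in 2 and 3 of 39, and early lineage regulators in 6 and 2 of 44, with Gata4 (48.4) and Hand2 (42.8) leading in 25 mM. Neuronal genes were hit in 11 and 10 of 30, with Gad1 (75.9) in 25 mM and Syt1 (49.2) in 1 mM on top. Effectors of liver, muscle and blood were hit in 2 and 3 of 36, fibroblast and feeder genes in 4 and 3 of 23, keratin-associated proteins in 2 and 2 of 54, and Zfp genes in 45 and 31 of 391. Within 1000 bp of a TSS, 17 Zfp genes were hit in 25 mM mESC, against 9.73 (4 to 16).

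**Figure D3:**
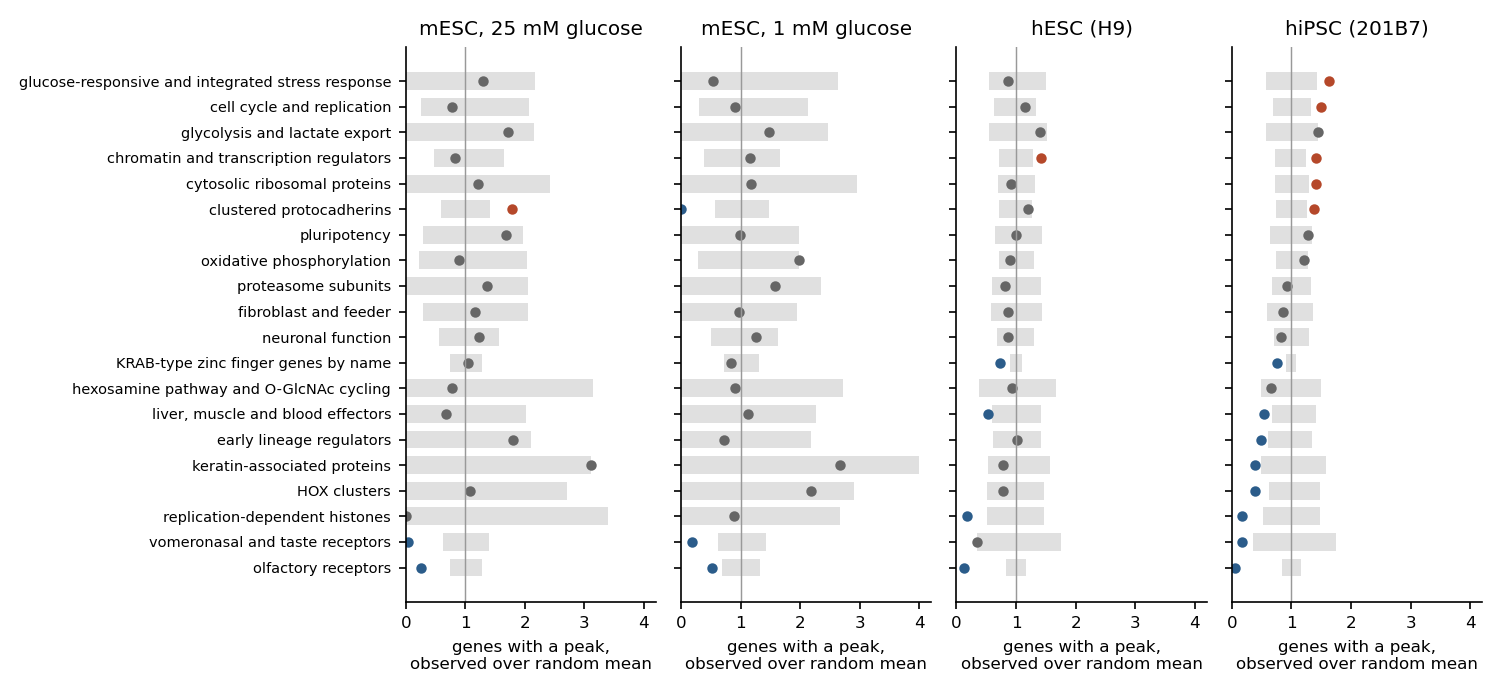
Members of each fixed gene list with a peak, as the observed count over the mean of 10000 length-matched random lists (x axis, fold), in each library: red points lie above, blue points below and grey points within the central 95% of random lists, which the grey bars show. Olfactory receptors are below in all 4 libraries, and chromatin regulators are above in hESC and hiPSC.

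The human libraries compare embryonic with induced pluripotent cells. In hESC the highest-scoring peaks in protein-coding genes lay in an intron of TTC34 (1157, chromosome 1, 2667943 to 2683649), KATNAL2, a katanin-like gene (611, intron, chromosome 18, 47019920 to 47030977), the mucin gene MUC12 (573), NPIPB5 (397), the 3' UTR of MAN1B1, a glycoprotein mannosidase gene (362), and the 3' UTRs of TSPAN4 and CHID1 (318). In hiPSC the top protein-coding genes were RASA4, a regulator of Ras (593, intron, chromosome 7, 102580436 to 102587971), KATNAL2 (557), RASA4B (498), UPK3BL1 (401), the kinesin gene KIF21B (373, intron, chromosome 1, 200989341 to 200993678), NPIPB5 (360) and PTPRN2 (354). RASA4 and RASA4B, NPIPB5, KATNAL2 and TTC34 lie in sequence that occurs in several copies, where reads cannot be assigned to 1 locus with certainty. Among protein-coding genes, peaks in hESC without a hiPSC peak within 1000 bp were strongest in ADGRD2 (295), in SKI, a repressor of TGF-beta signalling (276, intron, chromosome 1, 2281346 to 2284087), FGD3 (234), the ARAP3 promoter (232), and ADAMTS2, a collagen-processing protease gene (204). In hiPSC, strong peaks without a hESC peak nearby included those beside ARF1 and C1orf35 (336), in MYBPH (274), in SYMPK, a gene of messenger RNA 3' end processing (273), and at the promoter of TSSK6 and NDUFA13 (252). Of these, ARF1, C1orf35, MYBPH and KIF21B lie on the long arm of chromosome 1.

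Sharing was also counted between the human lists. These hold more peaks, called at another cutoff, and overlap more by placement alone, so their shares are not comparable with the mouse shares. Of the hESC peaks, 5843 (18.2%, interval 17.8 to 18.6%) overlapped a hiPSC peak, and 6005 hiPSC peaks (17.7%, 17.3 to 18.1%) overlapped a hESC peak. Random placement gave 3.32% and 3.17%, and GC-matched placement 12.7% and 12.3%, so the overlap was 5.49 and 5.58 times random and 1.43 and 1.44 times GC-matched placement. Of the top 100 peaks, 88 in hESC and 81 in hiPSC were shared, but of the highest-scoring quartile only 29.5% and 25.9%, and of the lowest-scoring quartile 12.97% and 14.2%. Several of the highest-scoring peaks in both lists lie in repeated genes, as given below. Repeats may raise scores in both lists, so sharing among the top peaks need not reflect the mark, and this was not tested. Among protein-coding genes, shared peaks with the highest smaller score lay in KATNAL2 (557), NPIPB5 (360), TTC34 (270.4), MUC12 (270.0), PTPRN2 (246), the guanylate kinase gene GUK1 (228), CCDC200 (213), the chaperone gene DNAJB6 (191), TMEM242 (187) and the transcriptional coactivator gene ZMIZ1 (183). Of 20033 protein-coding genes, 8752 (43.7%) had a peak in hESC, 9573 (47.8%) in hiPSC and 6286 in both, against 4548 for length-matched draws, while 2466 had one in hESC only and 3287 in hiPSC only. Near the TSS, 2337 and 3434 genes had a peak and 827 had one in both, against 412 (379 to 446).

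Several lists of broadly expressed genes lay above length-matched random lists in hiPSC, and 1 of them in hESC. Chromatin and transcription regulators were hit in 30 of 42 in hESC, against 21.1 (15 to 27) in random lists, and in 33 in hiPSC, against 23.3 (17 to 29). Of these, 28 were hit in both libraries. The leading members were the remodeller SMARCA4 (165), the H3K79 methyltransferase gene DOT1L (141) and KMT2B (137) in hESC, and the corepressor SIN3A (161), the maintenance DNA methyltransferase DNMT1 (155) and KMT2D (150) in hiPSC. Cytosolic ribosomal proteins were hit in 39 of 80 in hiPSC, against 27.6 (20 to 36), with RPL35 (178), RPS15 (142) and RPLP0 (136) on top. In hESC 22 were hit, against 24.2 (17 to 32), led by RPS3 (129) and RPL36 (128). Cell cycle genes were hit in 26 of 35 in hiPSC, against 17.3 (12 to 23), with MYC (275), the DNA polymerase gene POLE (157) and the replicative helicase gene MCM4 (101) leading, and in 18 in hESC, against 15.7 (10 to 21). The hiPSC peak in MYC (chromosome 8, 127737780 to 127739193) is placed at a promoter because a TSS is annotated within 1000 bp of its midpoint, and it holds 772 coding bases of the gene, and MYC was among the genes introduced into that line. Near the TSS the cell cycle count in hiPSC (11 against 6.39, 2 to 11) and the chromatin regulator count in hESC (5 against 4.08, 1 to 8) lay within the random range. At a score of at least 100 chromatin regulators in hESC (1.21 times the random mean) and ribosomal proteins in hiPSC (1.78 times) were also within it, and cell cycle genes in hiPSC were at 0.961 times the mean. The difference between hESC and hiPSC was not tested for any list.

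Stress response genes were also above random lists in hiPSC and within their range in hESC. Of 25 glucose-responsive and integrated stress response genes, 17 were hit in hiPSC, against 10.5 (6 to 15), and 8 in hESC, against 9.29 (5 to 14). Both libraries hit 7 of them, 10 were hit in hiPSC only and 1 in hESC only. The hiPSC list was led by the promoter of CHAC1, a glutathione-degrading enzyme gene induced by ATF4 (143, chromosome 15, 40952191 to 40954230), MLXIP, which encodes a glucose-sensing transcription factor (141), and the promoter of ATF3 (119), and the hESC list by MLXIPL (93.2), KLF10 (86.3) and PPP1R15A (84.4). Within 1000 bp of a TSS, 14 of the 25 were hit in hiPSC, against 4.68 (1 to 9), as were 9 of 21 glycolysis genes, against 3.75 (1 to 7). Over whole genes, glycolysis counts of 13 in hESC and 15 in hiPSC lay within the random range, with PFKL (115), PKM (103) and TPI1 (99.5) on top in hESC and PKM (120), ENO2 (103) and PFKL (94.3) in hiPSC. TXNIP had no peak in either human list. In the hexosamine pathway 5 and 4 of 12 genes were hit, with UAP1L1 (101) leading in hESC and GFPT2 (103) in hiPSC. OGA had a peak in hiPSC only (69.5, intron, chromosome 10, 101789105 to 101790019), and OGT in neither.

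Pluripotency genes were hit in 14 of 35 in hESC and 20 in hiPSC, both within the random range. The top members were JARID2 (107), PODXL (101) and PRDM14 (86.7) in hESC, and the Nodal antagonist gene LEFTY1 (179), JARID2 (141) and the Nodal co-receptor gene TDGF1 (121) in hiPSC. POU5F1 and NANOG had no peak in either list. SOX2 had a peak in hiPSC only (67.6, coding exon, chromosome 3, 181712354 to 181713542), which spans all 951 bases of its coding sequence. SOX2, like MYC, was introduced into 201B7. Reads from an introduced copy align to the same coding sequence, so the hiPSC peaks of SOX2 and MYC were not shown to reflect H4T71Gc at the endogenous genes.

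Lineage and tissue genes carried fewer peaks than length-matched genes in hiPSC. HOX genes were hit in 5 of 39, against 12.9 (8 to 19), and early lineage regulators in 8 of 44, against 16.4 (10 to 22), led by PAX7 (83.5), GATA2 (64.6) and SOX10 (61.4), although near the TSS the lineage count of 3 lay within the range of length-matched lists (7.92, 3 to 13) and below that of lists also matched on promoter GC content (9.48, 5 to 15). In hESC, 9 HOX genes and 15 lineage regulators, with PAX7 (91.4) and LHX2 (80.3) first, lay within the range. HOX genes and many histone, olfactory receptor, ZNF and keratin-associated genes lie in clusters. Random lists do not copy these clusters, so the ranges for these lists may be too narrow. Effectors of liver, muscle and blood were hit in 7 of 36 in hESC, against 13.4 (8 to 19), and 8 in hiPSC, against 14.95 (10 to 21). Both effector counts lay within the range of lists also matched on promoter GC content (10.3, 5 to 15, and 11.4, 7 to 17) and within the range near the TSS. Replication-dependent histones were hit in 2 of 69 in each, against 11.5 (6 to 17) and 11.4 (6 to 17), and both histone counts were within the range near the TSS with promoter GC content matched (5.92, 2 to 10, and 6.08, 2 to 11) and at a score of at least 100. Olfactory receptors were hit in 12 of 415 in hESC, against 94.3 (79 to 110), and 6 in hiPSC, against 100.4 (85 to 116). With promoter GC content matched, the olfactory counts were still below random lists (27.3, 19 to 36, and 29.7, 21 to 39), and near the TSS the hESC count of 5 was then within the range (8.66, 4 to 14). Genes named ZNF, many of which encode KRAB repressors, were hit in 168 of 508 in hESC, against 228 (206 to 249), and 195 in hiPSC, against 255 (233 to 277). Vomeronasal and taste receptors were hit in 2 of 31 in hESC, within the range, and 1 in hiPSC, against 5.72 (2 to 10), and keratin-associated proteins in 9 of 94 in hESC, within the range, and 4 in hiPSC, against 10.1 (5 to 16). With promoter GC content matched, these hiPSC counts of receptors and keratin-associated proteins were within the range (2.84, 1 to 5, and 8.86, 4 to 14). Clustered protocadherins were hit in 30 of 53 in hESC, within the range, and 37 in hiPSC, against 26.98 (20 to 34), in both cases through 9 peaks. With promoter GC content matched, the hESC count was above random lists as well (17.3, 11 to 23). Near the TSS they were below random lists in hESC (1 against 5.64) and at 0.458 times their mean in hiPSC. With promoter GC content also matched near the TSS, both protocadherin counts were within the range, at 0.528 times the mean in hESC and 1.10 times in hiPSC. Within the range in both libraries were proteasome subunits (11 and 14 of 32), oxidative phosphorylation genes (25 and 38 of 75), neuronal genes (14 and 14 of 30, led by GRIN1 at 134 and RBFOX3 at 137) and fibroblast and feeder genes (9 and 10 of 23, led by COL6A1 at 147 and COL5A1 at 117).

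The long arm of chromosome 1 (hg38 143184588 to 248956422, 983 protein-coding genes) held 2103 hiPSC peaks and 894 hESC peaks. Relative to the other autosomal sequence, the ratio of hiPSC to hESC peaks on the arm was 2.31 (bootstrap interval over 10 Mb bins 1.62 to 3.05), and the plain ratio of hiPSC to hESC peaks exceeded 1.2 in 9 of the 10 bins from 150 Mb to the chromosome end. The bin from 140 to 150 Mb, in which the arm starts, held 45 hiPSC and 55 hESC peaks. Several hiPSC genes named above lie on the long arm, ATF3 and LEFTY1 among them. Without chromosome 1, the hiPSC counts were 37 of 75 ribosomal proteins (against 25.6), 14 of 21 stress response genes (8.32), 30 of 37 chromatin regulators (20.2) and 25 of 34 cell cycle genes (16.5), all still above the random range. In hiPSC, chromosomes 20, 21 and 22 held 0.753, 0.496 and 0.761 times the number given by their GC content, against 1.04, 0.876 and 1.11 times in hESC.

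**Figure D4:**
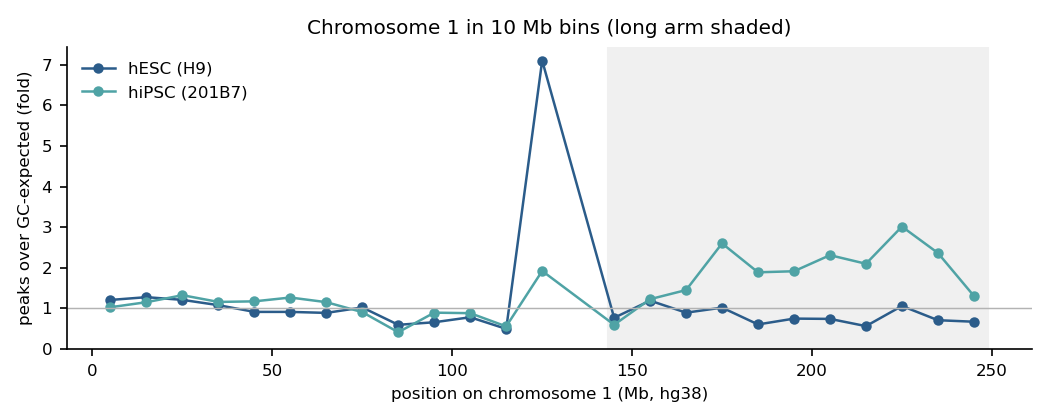
Peaks over the number given by GC content (y axis, fold) in 10 Mb bins along chromosome 1 (x axis, Mb, hg38) in hESC and hiPSC, with the long arm shaded and a line joining the bins on both sides of the centromere gap. From 170 to 240 Mb the hiPSC points lie between 1.89 and 3.02 and the hESC points between 0.565 and 1.06.

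Across species, the question was whether the same genes carry the mark. Of 15713 genes with matched symbols, 1459 had a peak in both 25 mM mESC and hESC, against 1393 (1353 to 1434) for length-matched draws, and 1561 in both 25 mM mESC and hiPSC, against 1490 (1449 to 1532). Counts as high came from 9 and 3 of the 10000 draws, which describe these lists and are no test across genes. The draws were matched on gene length and not on GC content, in which the peaks of both species are rich. For 1 mM mESC the counts were 1187 with hESC, against 1224 (1185 to 1264), and 1315 with hiPSC, against 1308 (1269 to 1348), both within the range. Members named in both species included the DNA polymerase gene POLE (33.1 in 25 mM mESC, 104 in hESC and 157 in hiPSC, each on its own list's scale) and the neuronal splicing factor gene RBFOX3 (42.7, 125 and 137). The excess for 25 mM mESC was small, 1.05 times in each case. For peaks near the TSS the values were 0.923 times with hESC and 1.11 times with hiPSC, and at a score of at least 50 they were 1.05 and 1.04 times, all within random ranges that rest on fewer genes. Whether 25 mM and 1 mM mESC differ in this overlap was not tested.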

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

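The tests of GC content, for the long arm of chromosome 1, for chromosomes 8 and 11 and for promoters and genes, were chosen only after the result was seen. The clustered protocadherins went opposite ways in the mouse lists, with 24 of 57 members holding a peak in 25 mM mESC, above the random lists, and 0 in 1 mM mESC, below them, and this difference was not tested. The 24 members rest on only 2 peaks, against 0 in 1 mM mESC, so they are not separate observations. Random lists do not copy such clustering. Sequences outside the assembled chromosomes, which the comparisons do not use, held 26 peaks in 25 mM mESC, 20 in 1 mM mESC, 210 in hESC and 144 in hiPSC.

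Peaks of hiPSC were dense on the long arm of chromosome 1 relative to hESC. The ratio on the arm, relative to other autosomal sequence, was 2.62 (bootstrap interval 1.78 to 3.54) outside genes and 2.17 (1.52 to 2.92) inside them, and the value of 2.62 outside genes argues against more H4T71Gc at the genes of the arm alone. GC content is also argued against as the whole cause, since the arm held 1.93 times (1.45 to 2.41) its GC-expected number of hiPSC peaks. The plain hiPSC to hESC ratio was 0.818 from 140 to 150 Mb and 1.13 from 150 to 160 Mb, so the rise did not span the whole arm. Extra copies of the arm in the hiPSC culture, a change known to recur in human pluripotent cells, or of part of it, may account for some of the rise. Peaks were called against input reads, which extra copies would also raise, so the calling can offset part of a gain. The hiPSC input, not analysed here, would test for extra copies. A difference of the mark between the cell lines over much of the arm, genes and intergenic sequence alike, also stays open and was not tested.

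Peaks were dense on chromosomes 8 and 11 in both mouse lists. With both chromosomes pooled, GC content is argued against, since the lower of the lists held 1.48 times (interval 1.29 to 1.70) the GC-expected number, and so is gene content, with 1.52 times (1.33 to 1.73) outside genes in the lower list. Extra copies of both chromosomes, gains of which recur in cultured mouse embryonic stem cells, are a candidate explanation, since peaks were raised inside and outside genes in both lists, with 1.48 (1.248 to 1.75) as the lowest of 4 values. The inputs were the control in peak calling, so the calling can offset part of a gain in copies. A comparison with the inputs would be needed to decide, and they were not analysed here. Outside genes the excess was 1.52 times in 25 mM and 2.04 times (1.78 to 2.297) in 1 mM mESC, a difference that was not tested, and no biological explanation was tested.

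Peaks lay at promoters and within genes more often than randomly placed peaks, and they were also richer in GC than the genome. After matching on GC content, promoter shares were 1.03 times the matched mean in 25 mM mESC, 0.5999 times in hESC and 0.921 in hiPSC. The share within genes was 0.954 times in 25 mM and 1.02 times in 1 mM mESC. GC content may account for these excesses over random placement. The promoter shares of hESC and hiPSC and the 25 mM share within genes lay below the matched range. GC content does not account for those deficits. As the whole cause it is argued against for promoters in 1 mM mESC (1.18 times), where the share stayed above the matched range. The same holds for genes in hESC (1.05 times) and hiPSC (1.17 times). Promoters are themselves rich in GC, so matching also removes part of any true preference for them, and whether GC content acts through chromatin or through amplification stays open. A preference of the mark for active genes was not tested, because no expression data were used here.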

How the results depend on the processing

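Leaving out chromosomes 8 and 11 or chromosome 1, and GC-matched placements for shared peaks, were chosen after seeing the data. Of 594 alternative values, 472 were counted as unchanged. A fold was unchanged if it kept its direction and side of the threshold. It was also unchanged, whatever its direction, if it lay inside the random range in both settings. A share had to stay within the main interval and a count within 1.5 times the main count. Of the others, 62 moved further, 40 fell back inside the random range and 5 newly left it. Another 15 changed direction with a value outside the range in either setting. No paired analysis was possible because each group is 1 library. Where no reason is given, the cause was not tested. Without the dense chromosomes, 107 of 108 values held, the exception being vomeronasal and taste receptors in hESC, at 0 times the random mean and now below the range. Autosomes only and merging peaks within 1000 bp changed no call or count beyond these bounds, GC-matched placement left every overlap of lists above its range, and the 2500 bp promoter has no bearing on the share within genes.

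Definitions moved shares by construction. A promoter of 2500 bp gave 8.72% in 25 mM mESC, 7.85% in 1 mM mESC, 11.3% in hESC and 14.3% in hiPSC. Any overlap of 1 bp gave promoter shares of 6.85%, 5.78%, 7.54% and 10.5%, and shares within genes of 49.5% in 25 mM mESC, 60.9% in hESC and 69.1% in hiPSC. All annotated genes gave 9.50%, 8.47%, 10.1% and 12.996% at promoters and 55.6%, 56.2%, 69.9% and 76.3% within genes. For sharing, a reciprocal overlap of 50% gave 1.60% and 1.83% in 25 mM and 1 mM mESC and 9.70% and 9.17% in hESC and hiPSC, and a distance of 1000 bp gave 3.33%, 3.86%, 27.2% and 26.9%. Equal numbers of top peaks gave 17.4% in hESC, and the upper part by score gave 23.01% in hESC and 20.8% in hiPSC.

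GC-matched placement gave promoter folds of 1.03 in 25 mM mESC, 0.5999 in hESC and 0.921 in hiPSC and folds within genes of 0.954 in 25 mM and 1.02 in 1 mM mESC. Random lists also matched on promoter GC brought olfactory receptors in 25 mM mESC (0.626 times the random mean) and 1 mM mESC (0.756), effectors of liver, muscle and blood in hESC (0.679) and hiPSC (0.7001), and in hiPSC vomeronasal and taste receptors (0.352) and keratin-associated proteins (0.452) inside the range, and put clustered protocadherins in hESC above it (1.73).

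Counting only peaks within 1000 bp of a TSS, which leaves fewer hits, gave 21 genes in both mouse and 827 in both human lists, and cross-species folds of 0.923 for 25 mM mESC with hESC and 1.11 with hiPSC. Zfp genes rose above the range in 25 mM mESC (1.75) and glycolysis genes in hiPSC (2.40). Clustered protocadherins turned to 0 in 25 mM mESC, 0.177 in hESC and 0.458 in hiPSC (with promoter GC also matched, a combination looked at after seeing the data, 0.528 and 1.10 in hESC and hiPSC, both inside the range), and in 1 mM mESC stayed at 0 but inside the range, as did olfactory receptors there (0.707). Chromatin regulators (1.23) and effectors of liver, muscle and blood (0.891) in hESC, and cell cycle genes (1.72), early lineage regulators (0.379) and the same effectors (0.798) in hiPSC, also fell inside it.

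A score of at least 50 left 549 and 380 peaks over 0.641 and 0.416 Mb in 25 mM and 1 mM mESC, with promoter shares of 7.31% and 6.63% and shares within genes of 43.9% and 46.4%, 1.05 and 1.11 times random placement and inside its range. Sharing fell to 0.366% and 0.531%, 7.49 and 7.14 times random but inside the range with so few peaks, and 11 genes were hit in both. Cross-species folds were 1.05 with hESC and 1.04 with hiPSC, inside the range. Glucose-responsive and stress response genes in 25 mM mESC rose above it (15.3). Olfactory (0.273) and vomeronasal and taste receptors (0.524) in 25 mM mESC, and these lists and protocadherins at 0 in 1 mM mESC, lost their call, and protocadherins in 25 mM mESC turned to 0.

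A score of at least 100 left 4 and 3 mouse peaks over 0.00728 and 0.00246 Mb, too few to read, and 2526 and 2621 peaks over 5.31 and 4.99 Mb in hESC and hiPSC. In 25 mM mESC promoters held 0% (fold 0) and genes 50.0% (1.18), in 1 mM mESC promoters 33.3% and genes 33.3% (0.810), and 0% of either list was shared. Genes held 63.8% in hESC and 72.5% in hiPSC, hiPSC promoters 9.10%, and 12.3% of hESC and 12.6% of hiPSC peaks were shared. The cross-species fold was 0 for 25 mM mESC with hESC and 0 with hiPSC. Protocadherins turned to 0 in 25 mM mESC, and olfactory, vomeronasal and taste receptors stood at 0 in 1 mM mESC, inside the range. In hESC chromatin regulators (1.21), histones (0) and effectors of liver, muscle and blood (0) lost their call. In hiPSC ribosomal proteins (1.78), histones (0), HOX genes (0), early lineage regulators (0), the same effectors (0.367), vomeronasal and taste receptors (0) and keratin-associated proteins (0) lost theirs, while cell cycle genes (0.961) and protocadherins (0) changed direction. This cutoff gave no value for the fold of shared mouse peaks, for 1 mM mESC across species or for mouse lists whose random lists held no hit. The unknown read depth limits every count of peaks, and the small number of strong mouse peaks limits the mouse lists.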

Other observations

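Several of the highest-scoring peaks on the assembled chromosomes in both human lists lay outside protein-coding genes, in repeated genes or where no gene is annotated. The highest hESC score, 3100, belongs to a peak on a sequence outside those chromosomes. All 17 annotated 5S ribosomal RNA genes of the array on the long arm of chromosome 1 were covered in both hESC and hiPSC, with top scores of 1575 (hg38 228627125 to 228647273) and 1122 (228608322 to 228621623), while the 4 annotated U1 small nuclear RNA genes of the RNU1 family had no peak in either list. The pseudogene CROCCP2 (1442 in hESC and 751 in hiPSC), the lncRNA ENSG00000283360 (754 and 1638), the lncRNA LINC00665 (700 and 1208), the pseudogene REXO1L12P (830 and 538) and the lncRNA DANT2 (573 and 920) were other examples. Several of these lie in tandem or segmental duplications, where the number of copies in the cells need not match the assembly. These loci were chosen after their values were seen.

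Long noncoding RNA genes were hit less often than protein-coding genes and about equally in both human lists, 3472 of 18866 (18.4%) in hESC and 3553 (18.8%) in hiPSC, although they are also shorter, with a median length of 6280 bp against 27471 bp. In mouse, 340 of 5854 long intergenic noncoding RNA genes (5.81%) were hit in 25 mM mESC and 275 (4.70%) in 1 mM mESC. Processed pseudogenes were hit in 1.26% and 1.07% of cases in mouse and in 3.21% and 3.12% in hESC and hiPSC. In hESC the part of chromosome 1 from 120 to 130 Mb, which includes the centromere, held 177 peaks, 7.10 times the number given by GC content, against 35 in hiPSC.

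Of the 4 factors introduced into 201B7, SOX2 and MYC had hiPSC peaks that touch their coding sequence, and POU5F1 and KLF4 had none. The SOX2 peak (67.6, chromosome 3, 181712354 to 181713542) held all 951 coding bases of the gene, while hESC had no SOX2 peak. In MYC the hiPSC peaks had scores of 275 and 100.2 (chromosome 8, 127737780 to 127739193 and 127739905 to 127740949) and held 772 and 554 annotated coding bases. The single hESC peak, with a score of 58.3, held 249. The 2252 coding bases annotated in MYC join all transcript models and are not the length of a single coding sequence. The part of the introduced MYC sequence that these peaks cover was therefore not measured. Whether reads from the introduced copies contribute was not tested. These genes were looked at after the values of SOX2 and MYC were seen.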
